A study of Homo sapiens with 8 samples.

How the data were processed

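RNA of single fixed cells was measured in 8 libraries of THP-1 cells, 4 labelled WT and 4 labelled FOLR2 KO, all unstimulated. Per the labels' protocols, cells grown in RPMI with 10% FBS and 1% antibiotic/antimycotic were differentiated with PMA, rested for 24 h, kept for 4 h in medium without serum, depleted of dead cells with magnetic beads, fixed by the 10x Genomics Flex procedure and sequenced on a NovaSeq X Plus. Flex reads each gene through probes designed for it, so a gene without probes has no value and a transcript that keeps its probed part is counted even if an edit has inactivated it.

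The deposited matrices hold raw UMI counts per gene and cell, not normalized, made by the authors with Cell Ranger 7.1.0, per the file headers, on GRCh38, per the submitters' processing notes. The probe set and its version are not given in the sources used here. Each matrix lists the same 18082 features, and its barcodes had already been limited to cells (no barcode had fewer than 485 UMIs). The barcode lists of 7 libraries were used; any pair of them shared 15.1% to 28.6% of the droplet barcodes of the smaller library, and each list carried a probe barcode of its own. A doublet caller was not run. The alternative without the 5% of cells with most UMIs stands in its place.

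From 75514 barcodes, 75372 cells were kept by a minimum of 500 detected genes and a maximum of 20% of UMIs from the 11 mitochondrially encoded features, which removed 142. Counts were summed per library, because cells are not replicates, to 60592149 to 208315477 UMIs per library. At this depth 1 CPM stands for about 60 UMIs or more, so that counting error is small beside the spread between libraries for all but the lowest genes; FOLR2 in KO, at 10 to 62 UMIs, is one of those. Replicates of a group differed by far more than sampling noise (chi-square per degree of freedom 38.6 to 205), so no library was counted as a copy of another.

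Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (TMM, filterByExpr with a minimum count of 10, robust quasi-likelihood F test, two-sided, no covariates, all 8 libraries), with Benjamini-Hochberg adjustment at 0.05 over the 13636 genes that passed the filter; 4446 features did not. A test against 1.5-fold used glmTreat on the same fit. The common biological coefficient of variation was 0.168. On simulated counts for 13520 genes, with 200 changed, this procedure recovered 67.2% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 97.0% of those changed 4-fold, with 6 false calls (3.47% of calls), and called 0 of 30 unchanged lists. The simulated genes varied independently of each other, and the unchanged lists were drawn at random. The 0 of 30 therefore does not show how camera acts on lists of correlated genes. The 32 gene lists named in the results were fixed before the data were examined; 30 had at least 5 tested members and were tested with camera of limma 3.58.1 (preset correlation 0.01), with camera using an estimated correlation and with fry beside it, adjusted over the lists. Members were matched by symbol, older symbols included. Fry asks whether a list's genes move on balance one way and does not compare them with other genes.

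Named genes followed a rule fixed before the data were examined: FOLR2; the 12 genes with the largest rise and the 12 with the largest fall among genes passing the test with fully separated groups and a mean of at least 20 CPM in the higher group; in each list up to 4 passing members with at least 5 CPM, the 2 of largest rise and the 2 of largest fall; and NLRP3, PYCARD, GSDMD, IL1B and IL18 whatever their result. This gave 118 genes. XIST and Y-linked genes were left out, and CASP1 and HLA genes were not analysed here. Gene positions are those of GENCODE release 29 on GRCh38, which placed 18076 features.

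Shares of cells with a UMI were computed after seeded thinning of each cell to 2400 UMIs and compared by a two-sided exact permutation test of 4 against 4 libraries, which cannot go below p = 0.0286, adjusted over 10 genes. For clusters, 2500 cells per library were drawn, 2000 variable genes were centred and scaled within each library, and 30 principal components and 15 nearest neighbours (scikit-learn 1.9.0) were passed to Leiden clustering (leidenalg 0.10.2, resolution 0.5). Counts summed per library and cluster were tested as above in clusters with at least 50 cells in every library.

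The remaining steps were chosen after the data had been seen. Runs of neighbouring genes were searched over 9555 genes with at least 8 CPM on 23 chromosomes, against 200 permutations of gene order, and a run of at least 20 genes with a median beyond 0.3 on the log2 scale was taken as shifted. The null was first drawn from 4 chromosomes only and then widened to all 23, which left 5 shifted runs. Cells with at least 3000 UMIs were assigned to the 12q-low or the 12q-high class by the log likelihood ratio (beyond 3 either way) of their 12q UMIs. The shares compared were 0.628% in KO and 1.22% in WT. The 12q set held 166 genes of the run, with at least 8 CPM in the higher group and a log2 change within 1.5 either way. Interferon genes and genes called higher were taken out of the 12q set in a revision of this score. Comparisons restricted to replicates 1 and 2, to replicates 3 and 4, to genes outside the runs or to 1 cell class, and the depth of replicates as a term, were added likewise.

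Alternatives fixed in advance were a replicate block, DESeq2 1.42.0, limma-voom, DESeq2 size factors, upper quartile scaling, library totals, other gene and cell filters, thinning to the smallest library, removal of the cells with most UMIs or of cells with a proliferation UMI, each library left out in turn, other set tests, other thinning depths and other cluster settings. For DESeq2 the lists were tested on its Wald statistics; the list test of the main comparison already uses voom values, so limma-voom gave no separate list result. Cell handling used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.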

Results

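The series profiled THP-1 cells, a human monocytic leukaemia line, after the phorbol ester PMA (an activator of protein kinase C) had turned them into adherent, macrophage-like cells. Wild-type (WT) cells were compared with cells in which FOLR2 had been knocked out (KO). FOLR2 encodes folate receptor beta, a membrane-anchored folate-binding protein of macrophages, and the title of the series places it in the control of the NLRP3 inflammasome and of pyroptosis, the lytic cell death that this complex can start. No stimulus of the inflammasome is named in the labels, so the comparison asked how the resting transcriptomes of WT and KO macrophages differed. Single fixed cells were read with a probe-based assay, in which pairs of probes hybridise to each transcript and are counted by unique molecular identifiers (UMIs). There were 8 libraries, 4 WT and 4 KO, with 7117 to 12497 cells each after filtering and 75372 cells in all. The libraries held 60592149 to 208315477 UMIs, with a median of 6659 to 13985 UMIs per cell, and replicates 1 and 2 of both groups were shallower than replicates 3 and 4. Values below are TMM-normalised CPM of UMIs summed per library, given as mean ± SD with n = 4 per group, and log2 changes are KO against WT with their standard error (SE). Adjusted p-values are from edgeR's quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment over 13636 genes. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

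FOLR2 RNA was low in WT cells and fell in the KO cells. FOLR2 (ENSG00000165457; GRCh38 chromosome 11, 72216601 to 72221950, plus strand, a protein-coding gene) stood at 2.79, 1.95, 1.66 and 2.20 CPM in WT replicates 1 to 4 and at 0.625, 0.148, 0.402 and 0.379 CPM in KO replicates 1 to 4. These levels rested on 190, 156, 199 and 461 UMIs in the WT libraries and on 37, 10, 59 and 62 UMIs in the KO libraries. The group means were 2.15 ± 0.48 CPM and 0.389 ± 0.195 CPM, a log2 change of -2.47 (SE 0.34, adjusted p = 7.3e-04), and each of the 4 KO libraries lay below each of the 4 WT libraries. The KO level was 18.1% of the WT level. The position of the edit relative to the probes is not stated, so the UMIs that were left do not show whether functional transcript was made. In replicates 1 and 2 alone, a subset chosen after seeing the data, the log2 change was -2.62 and the adjusted p = 0.058.

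The WT and KO transcriptomes were far apart in unstimulated cells. The genes with the largest falls included PLPP3, a lipid phosphate phosphatase, at 28.3 ± 11.6 CPM in WT and 0.180 ± 0.086 CPM in KO (log2 change -7.30, SE 0.43, adjusted p = 1.1e-05). RAP2A, a small GTPase of the Ras family, fell from 52.1 ± 5.4 to 1.32 ± 0.19 CPM (log2 change -5.31, SE 0.14), and TRIO and KALRN fell by 4.13 and 2.88 on the log2 scale. GLDN, KIRREL1, CEMIP, DMRT3, HVCN1 (a voltage-gated proton channel), LRRC4B, CKAP4 and GOLGA7B made up the other large falls among genes with at least 20 CPM in the higher group, with log2 changes of -5.67 to -2.58. Among the largest rises on the log2 scale were NLRP2 (3.75), the cancer-testis gene MAGEB2 (3.67), the fatty-acid-binding protein gene FABP3 (3.24), NPTX1 (2.31) and ANKRD18A (2.39). A further 6 of the 12 genes with the largest rises under the same cut, IFIT1, IFIT2, IFIT3, IFI44, MX1 and RSAD2, were antiviral genes of the type I interferon response.

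In all, 2165 genes were higher and 2342 lower in KO, 33.1% of the genes tested, and 866 differed by more than 1.5-fold (257 higher, 609 lower). The 4 KO libraries lay entirely above or below the 4 WT libraries for 32.8% of all genes tested, where chance gives 2.86%. The first principal component held 64.7% of the variance and separated the genotypes. Within the shallower replicates 1 and 2 alone the counts were 1071 higher, 1409 lower and 108 past 1.5-fold, and within replicates 3 and 4 alone they were 2199, 2508 and 1339.

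**Figure D1:**
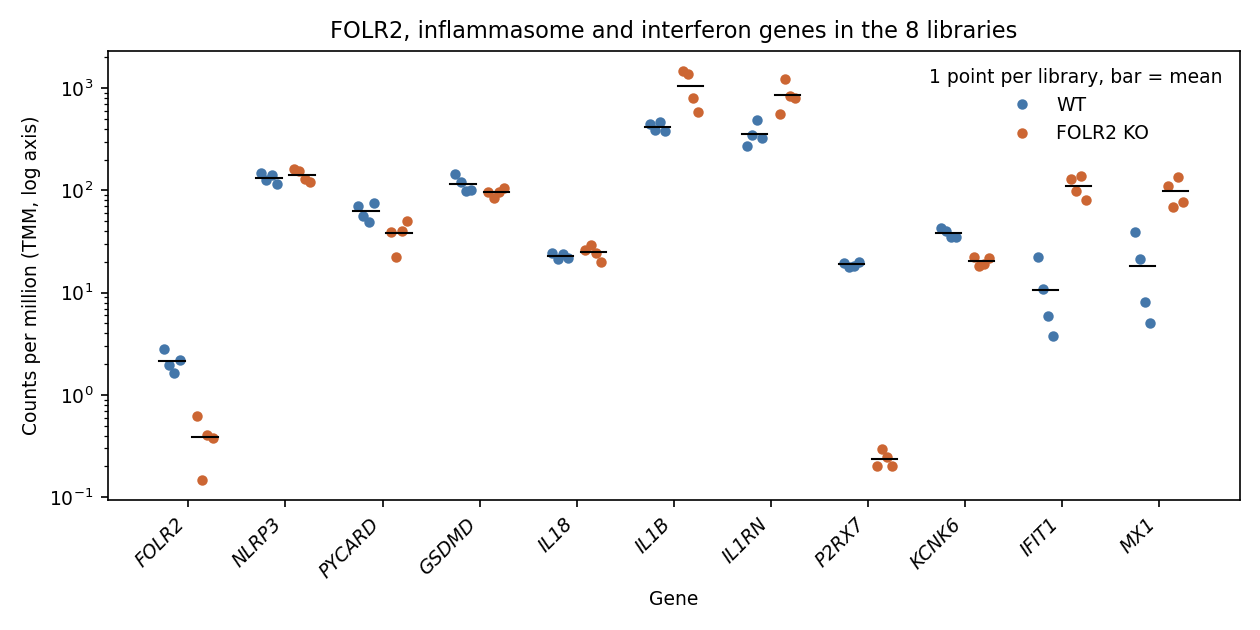
CPM of 11 genes (log axis) in each of the 4 WT and 4 KO libraries; points are libraries and bars are group means. FOLR2, P2RX7 and KCNK6 lay lower and IL1B, IL1RN, IFIT1 and MX1 higher in every KO library, while the NLRP3 and IL18 levels of the groups overlapped.

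Inflammasome genes moved in both directions, and NLRP3 itself was not among those that passed. NLRP3, the sensor, stood at 133 ± 14.3 CPM in WT and 142 ± 20.4 CPM in KO (log2 change 0.10, SE 0.12, adjusted p = 0.544). IL1B, the cytokine that the inflammasome matures, rose from 419.8 ± 40.8 to 1058 ± 431 CPM (log2 change 1.33, SE 0.27, adjusted p = 0.0047), and IL1RN, its receptor antagonist, rose from 358 ± 92.5 to 854 ± 279 CPM (log2 change 1.26, SE 0.25). P2RX7, the ATP-gated channel whose opening triggers NLRP3, fell from 18.9 ± 1.1 to 0.237 ± 0.045 CPM (log2 change -6.33, SE 0.15, adjusted p = 4.3e-08). KCNK6, a potassium channel gene, fell by 0.91 on the log2 scale, and PYCARD, the adaptor ASC, fell from 62.8 ± 11.8 to 38.1 ± 11.7 CPM (log2 change -0.72, SE 0.23, adjusted p = 0.036). GSDMD, the pore-forming executor of pyroptosis, had a log2 change of -0.27 (SE 0.12, adjusted p = 0.121) and IL18 one of 0.14 (SE 0.12, adjusted p = 0.384). Of the 27 tested members of the inflammasome and pyroptosis list, 5 rose, 5 fell and 17 did not pass; adjusted over the list alone, 7 rose and 5 fell. The list as a whole was not called by camera (adjusted p = 0.702), and its median of 0.13, its mean of -0.11 and the downward direction of fry differed in sign. P2RX7 lies within a stretch of chromosome 12 in which nearly every gene was lower in KO. The PYCARD call was lost, with adjusted p = 0.0562 to 0.084, without any 1 of WT replicates 1, 2 or 4 or KO replicates 1 or 3. CASP1 was not analysed here.

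The type I interferon response rose in KO cells. Of 35 interferon-response genes, 30 rose, none fell and 5 did not pass, and adjusted over the list alone 32 rose; the list median was 1.40 on the log2 scale. IFIT1, which binds foreign RNA caps, rose from 10.7 ± 8.3 to 111 ± 26.5 CPM (log2 change 3.40, SE 0.51, adjusted p = 0.0011). MX1, a dynamin-like antiviral GTPase, rose from 18.4 ± 15.6 to 97.8 ± 30.5 CPM (log2 change 2.42, SE 0.57, adjusted p = 0.011), and RSAD2 (viperin) rose by 2.28. Camera called the list (adjusted p = 1.3e-14), but not when the correlation between genes was estimated (adjusted p = 0.935 with an estimated correlation); fry, which asks only whether the genes of a list move together, called it (adjusted p = 0.027).

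Nuclear genes of oxidative phosphorylation were lower or did not pass. Of 36 genes, none rose, 12 fell (13 adjusted over the list alone) and 24 did not pass, with a median log2 change of -0.21. The largest falls of this list were COX6A1, a subunit of cytochrome c oxidase, from 146 ± 13.9 to 82.3 ± 10.2 CPM (log2 change -0.83, SE 0.11), and UQCRQ, of complex III, from 139 ± 12.7 to 86.2 ± 6.9 CPM (log2 change -0.69, SE 0.09); both lie in chromosomal stretches that shifted as a whole. Camera called the list (adjusted p = 0.0027), with adjusted p = 0.335 with an estimated correlation, and fry called it (adjusted p = 9.0e-04). Of the 12 members that fell, 5 lie in such stretches and 7 outside them. The mitochondrially encoded genes pointed the other way, with 4 of 11 higher (4 adjusted over the list alone), none lower and a median of 0.35, but the list was not called (camera adjusted p = 0.0719), and the median share of UMIs from these genes per cell was 1.61% ± 0.32 in KO and 1.19% ± 0.22 in WT. Glycolysis genes were split, with 1 of 19 higher and 4 lower (the same counts adjusted over the list alone): PFKFB3, which makes the activator of phosphofructokinase, rose by 0.66 and GPI fell by 0.38.

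Genes of folate transport and one-carbon metabolism were more often lower than higher. Of 25 tested, 2 rose and 8 fell, with the same counts adjusted over the list alone and a median of -0.16. ALDH1L2, a mitochondrial 10-formyltetrahydrofolate dehydrogenase, fell from 11.8 ± 2.95 to 3.13 ± 1.04 CPM (log2 change -1.91, SE 0.26). MTRR and MTHFD2L both rose by 0.68. Camera did not call the list (adjusted p = 0.222) and fry did (adjusted p = 0.0445). ALDH1L2 and MTRR lie in the shifted chromosomal stretches, as do 4 of the 8 members that fell and 1 of the 2 that rose.

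Macrophage markers were called in both directions, and their list was not called. Of 25 macrophage markers, 9 rose and 2 fell (the same adjusted over the list alone). LPL, lipoprotein lipase, rose from 427 ± 89.9 to 1726 ± 212 CPM (log2 change 2.01, SE 0.16, adjusted p = 4.6e-05) and APOE from 235 ± 48.9 to 609 ± 203 CPM (log2 change 1.37, SE 0.23), while CD9, a tetraspanin, fell by 0.96 and ITGAM, the alpha chain of complement receptor 3, fell from 135 ± 29.7 to 66.3 ± 8.0 CPM (log2 change -1.02, SE 0.15). Of 16 markers of the resident macrophages that carry FOLR2 in tissue, 4 rose (5 adjusted over the list alone) and 2 fell: NRP1 rose by 0.70 and PLTP, a phospholipid transfer protein, fell by 1.37. Among 29 genes of Fc and complement receptors and phagocytosis, 5 rose and 5 fell, also adjusted over the list alone. The receptor tyrosine kinase AXL rose by 1.22, the scavenger receptor CD36 rose from 138 ± 12.2 to 287 ± 70.5 CPM, and the HDL receptor SCARB1 fell by 1.32. SCARB1 lies in the lowered stretch of chromosome 12, and 3 of the 5 members that fell lie in shifted stretches. Of 36 lysosome genes 11 rose and none fell, adjusted over the list alone too, led by the acid lipase LIPA (log2 change 1.00, SE 0.18), and of 15 genes of cholesterol efflux 6 rose (7 adjusted over the list alone) and 1 fell. Cholesterol synthesis had 1 of 23 genes higher and 7 lower, also adjusted over the list alone, with MVK, mevalonate kinase, down by 1.49; 4 of those 7 lie in the chromosomal stretches. None of these 6 lists was called by camera (adjusted p = 0.221, 0.156, 0.983, 0.0719, 0.156 and 0.124 in this order).

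Antigen presentation, receptor signalling and activation genes also went both ways. CD74, the invariant chain of MHC class II, fell from 264 ± 19.9 to 100.2 ± 14.4 CPM (log2 change -1.40, SE 0.11, adjusted p = 4.7e-05) and lies in a stretch of chromosome 5 that was lower as a whole; it was the 1 of 4 measured class II genes that passed, and adjusted over the list alone IFI30, a lysosomal thiol reductase singled out after its values were seen, rose (log2 change 0.82). B2M, the light chain of MHC class I, rose by 0.60, while the trimming peptidases ERAP1 and ERAP2 fell by 0.68 and 0.66. The class I list had 1 of 12 higher and 5 lower, also adjusted over the list alone (camera adjusted p = 0.222). ERAP1 and ERAP2 lie in the same stretch of chromosome 5 as CD74, and are the 2 of those 5 in shifted stretches. HLA genes were not analysed here. In Toll-like receptor signalling, 6 of 24 rose and 3 fell, also adjusted over the list alone, among them TLR1 (0.80) and the adaptor MYD88 (0.50); fry called this list upward (adjusted p = 0.0445) and camera did not (adjusted p = 0.546). Of 30 NF-kB cytokines and targets, 5 rose and 2 fell, also adjusted over the list alone; the NF-kB subunit REL rose by 0.63 and the adhesion molecule ICAM1 fell by 0.55 (camera adjusted p = 0.597). Of 20 genes of the PMA and protein kinase C response, 7 rose and 4 fell (9 and 4 adjusted over the list alone), with TNFRSF9 down by 0.88 (camera adjusted p = 0.222). Immediate early genes had 4 of 27 higher and 5 lower, also adjusted over the list alone: EGR3 rose by 1.62, while KLF4 fell by 0.94 and the phosphatase DUSP2 fell by 1.18 (camera adjusted p = 0.699).

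Stress programmes were mixed. Of 19 heat shock genes, 4 rose and 1 fell, also adjusted over the list alone, with the chaperone HSPA1A up from 5.85 ± 4.76 to 23.8 ± 3.75 CPM (log2 change 2.05, SE 0.53, adjusted p = 0.016; its near-identical copy HSPA1B makes the assignment uncertain) and DNAJB4 up by 0.85. Among 12q-low cells alone, a comparison chosen after seeing the data, the HSPA1A change was -0.0807 (adjusted p = 0.849), so neither its call nor its direction held there. Of 24 NRF2 and oxidative stress genes, 5 rose and 4 fell, also adjusted over the list alone: GCLC, the catalytic subunit of glutathione synthesis, rose by 0.83 and the thioredoxin reductase TXNRD1 fell by 0.74. TXNRD1 lies in the lowered stretch of chromosome 12, and 2 of the 4 members that fell lie in shifted stretches. Among 27 amino acid and integrated stress response genes 3 rose and 8 fell, and among 22 unfolded protein response genes 2 rose and 5 fell, with the same counts adjusted over each list alone; the amino acid transporter SLC7A5 rose by 0.70 and the chaperone HSP90B1 fell by 0.85. Of 18 hypoxia genes 2 rose (1 adjusted over the list alone) and 2 fell: the carbonic anhydrase CA12 rose by 1.73 and VEGFA, the angiogenic growth factor, fell by 1.52. Camera called none of these 5 lists (adjusted p = 0.151, 0.585, 0.546, 0.585 and 0.652 in this order).

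Cell-cycle, survival and adhesion genes were called in both directions. Of 40 S phase genes 1 rose and 9 fell (1 and 3 adjusted over the list alone), with the uracil glycosylase UNG down by 1.39, and of 51 G2 and M phase genes 6 rose and 5 fell (3 and 4 adjusted over the list alone), with the kinase AURKA up by 0.53 and TMPO down by 1.17. Of 28 apoptosis genes 5 rose (6 adjusted over the list alone) and 6 fell; the caspase-8 regulator CFLAR rose by 0.56 and the pro-apoptotic BIK fell by 0.71. Of 30 integrin and adhesion genes 5 rose and 8 fell, also adjusted over the list alone: ITGB3, the beta chain of the vitronectin receptor, rose from 34.7 ± 11.1 to 98.1 ± 30 CPM (log2 change 1.5, SE 0.27) and PTK2, focal adhesion kinase, fell by 1.70. Of 24 matrix genes 5 rose (6 adjusted over the list alone) and 5 fell, with the protease MMP7 up by 1.77. Of 20 monocyte and progenitor markers 2 rose (1 adjusted over the list alone) and 4 fell, with the granulocytic factor CEBPE down by 2.02. Camera called none of these 6 lists (adjusted p = 0.124, 0.959, 0.959, 0.546, 0.994 and 0.652 in this order). Markers of other cell types gave little: of 9 T, NK and B cell markers 1 fell (CD79B, log2 change -1.72, chosen after its values were seen), and of 5 epithelial and fibroblast and 3 erythroid and megakaryocyte markers tested none passed, also adjusted over each list alone. Camera's adjusted p was 0.959 for the T, NK and B cell list and 0.546 for the epithelial and fibroblast list. In the lists of G2 and M phase, Fc receptors, apoptosis, matrix genes and T, NK and B cell markers, the median, the mean or the direction of a list test differed in sign, and all of these medians lay between -0.05 and 0.04.

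**Figure D2:**
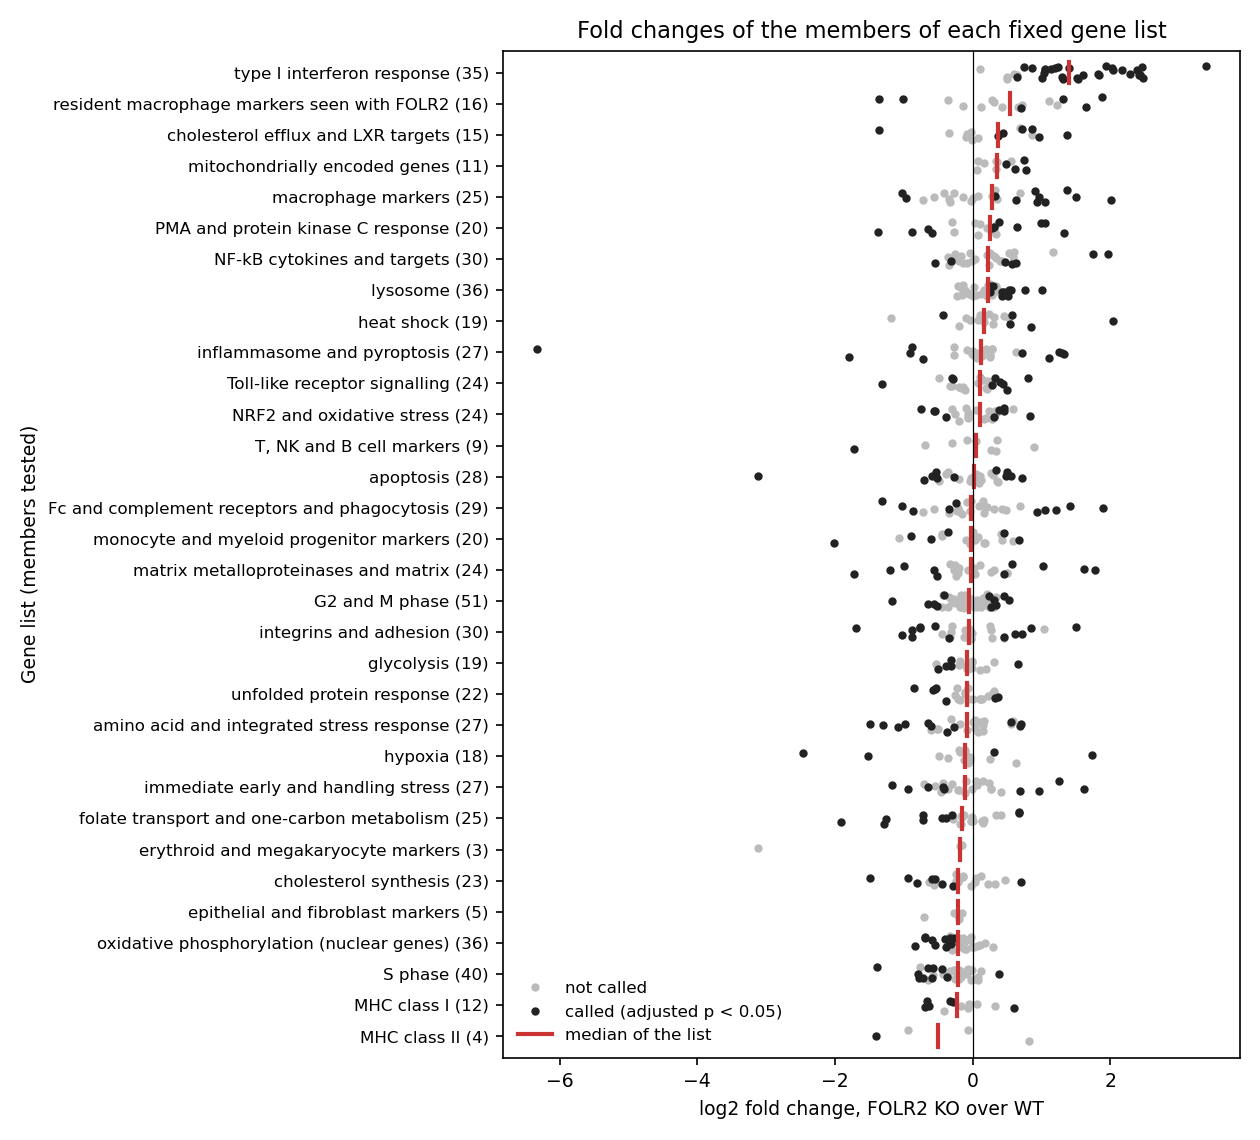
Log2 change (KO against WT) of the members of the gene lists fixed before the data were examined; each point is a gene and each bar is the median of its list. The interferon list is centred at 1.40 and the oxidative phosphorylation list at -0.21.

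Runs of neighbouring genes were shifted together in KO. On the long arm of chromosome 12, between 80792520 and 131851783 (GRCh38, positions of GENCODE release 29), 178 of 186 genes were lower in KO and 166 were called lower, with a median log2 change of -0.90, or 0.536 of the WT level. On chromosome 5 the short arm (196871 to 43707405) was higher, at a median of 0.44 with 61 of 69 genes above 0, and the long arm (50396192 to 181261139) was lower, at -0.45 with 334 of 365 genes below 0. Chromosome 21 (14371115 to 46665124) had a median of -0.42, with 84 of 93 genes lower, and a short stretch of chromosome 10 (97713173 to 101843920) had a median of -0.35, with 26 of 33 genes lower. Each of these runs was shifted in each of the 4 KO libraries. Together these 5 runs held 1013 of the genes tested, 668 of the genes called and 5 of the 24 genes named for their fold change: MX1 rose against the direction of its run, TRIO fell against the direction of its own, and HVCN1, CKAP4 and GOLGA7B fell as their runs did. With these regions left out, an alternative chosen after seeing the data, 1834 genes were higher, 1844 lower and 644 past 1.5-fold, and camera still called the interferon list (adjusted p = 4.1e-14) and the oxidative phosphorylation list (adjusted p = 0.0044). Over all genes neither call stood with an estimated correlation (adjusted p = 0.935 and 0.335), which was not tried with the regions left out.

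**Figure D3:**
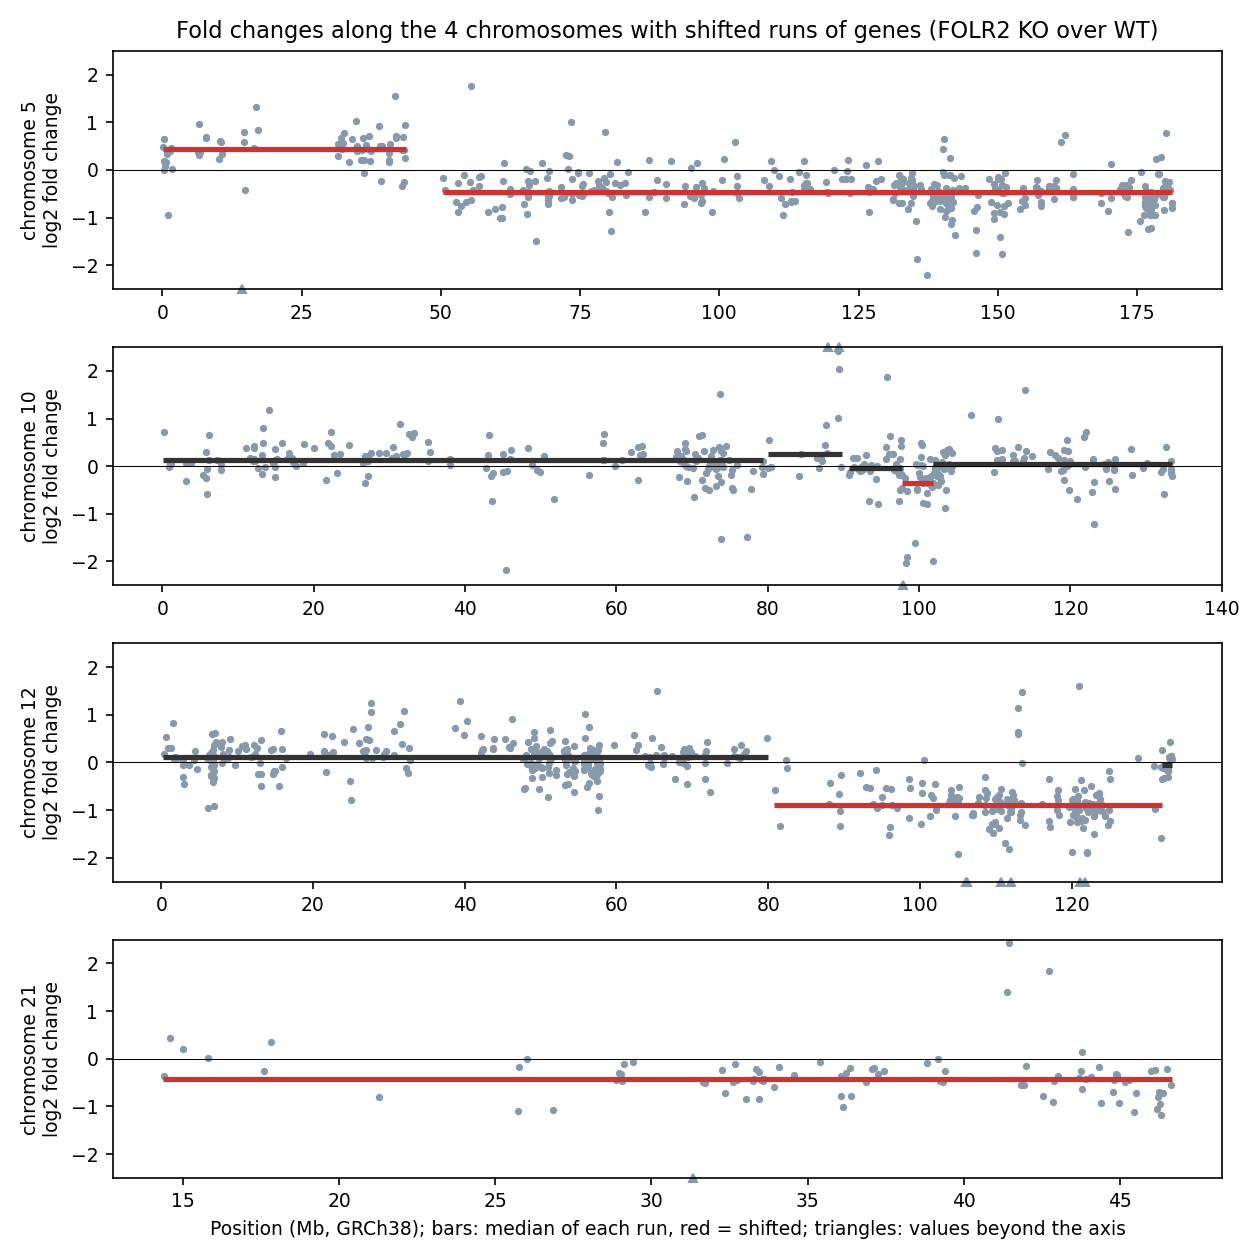
Log2 change (KO against WT) of genes by position (Mb) on chromosomes 5, 10, 12 and 21; each point is a gene and the lines are the medians of the runs. The run on 12q lies at -0.90 and the short arm of chromosome 5 at 0.44.

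A minority of WT cells carried the low 12q share of UMIs that nearly all KO cells had. Cells were sorted by the share of their UMIs that came from 166 genes of the 12q run, into a 12q-low class, a 12q-high class and cells too near the boundary to assign. Genes with a log2 change beyond 1.5, P2RX7 among them, did not enter the sorting. In WT replicates 1 to 4, 19.1%, 13.8%, 4.07% and 2.24% of cells were 12q-low, and in KO replicates 1 to 4, 95.1%, 94.9%, 96.4% and 96.2% were; 8.11%, 7.40%, 3.72% and 1.56% of WT cells and 4.24%, 4.52%, 2.79% and 3.02% of KO cells lay near the boundary. These classes are ranges of a score, not cell types. Chromosome 5p, which did not enter the sorting, took a larger share of UMIs in 12q-low than in 12q-high WT cells, by 1.36-fold to 1.44-fold over the 4 libraries, and chromosome 21 a smaller one, by 0.793 to 0.815; for 5q the ratios ran from 0.859 to 1.01. P2RX7 stood at 5.49, 5.10, 4.39 and 5.78 CPM (here of the total of each class, without TMM) in the 12q-low cells of WT replicates 1 to 4, at 24.4, 20.2, 18.9 and 20.5 in the 12q-high cells, and at 0.195, 0.213, 0.206 and 0.199 in the 12q-low cells of the KO libraries.

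Comparing KO with WT among 12q-low cells alone, an alternative chosen after seeing the data, changed the counts most. It called 320 genes higher, 443 lower and 102 past 1.5-fold. For genes of the 12q run that entered the sorting, the choice of these cells takes away most of the difference by construction. When 12q-high WT cells were thinned to the same totals instead, to match the smaller number of UMIs, the counts were 1883 higher, 2053 lower and 789 past 1.5-fold. Of the genes called over all cells, 4231 could be tested among 12q-low cells; 653 (15.4%) kept the call and 429 had the opposite sign. Of the 866 genes past 1.5-fold over all cells, 717 could be tested; 691 had the same sign and the median ratio of the log2 changes was 0.517. Among the genes that remained called were FOLR2 (log2 change -2.45, adjusted p = 0.0078), IFIT1 (3.20, adjusted p = 0.0019), MX1 (2.28, adjusted p = 0.014), P2RX7 (-4.62, adjusted p = 7.0e-06), PLPP3 (-7.22), RAP2A (-4.69), CD74 (-1.34), APOE (1.26) and LPL (0.75). Those no longer called included IL1B (1.04, adjusted p = 0.0796), IL1RN (0.38, adjusted p = 0.423), KCNK6 (-0.41, adjusted p = 0.0704), PYCARD (-0.22, adjusted p = 0.610) and CD36 (0.36, adjusted p = 0.275). HSPA1A and, within the 12q run, UNG, TMPO, COX6A1 and HSP90B1 lost both call and direction. NLRP3 had a log2 change of -0.13 (adjusted p = 0.533) there.

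**Figure D4:**
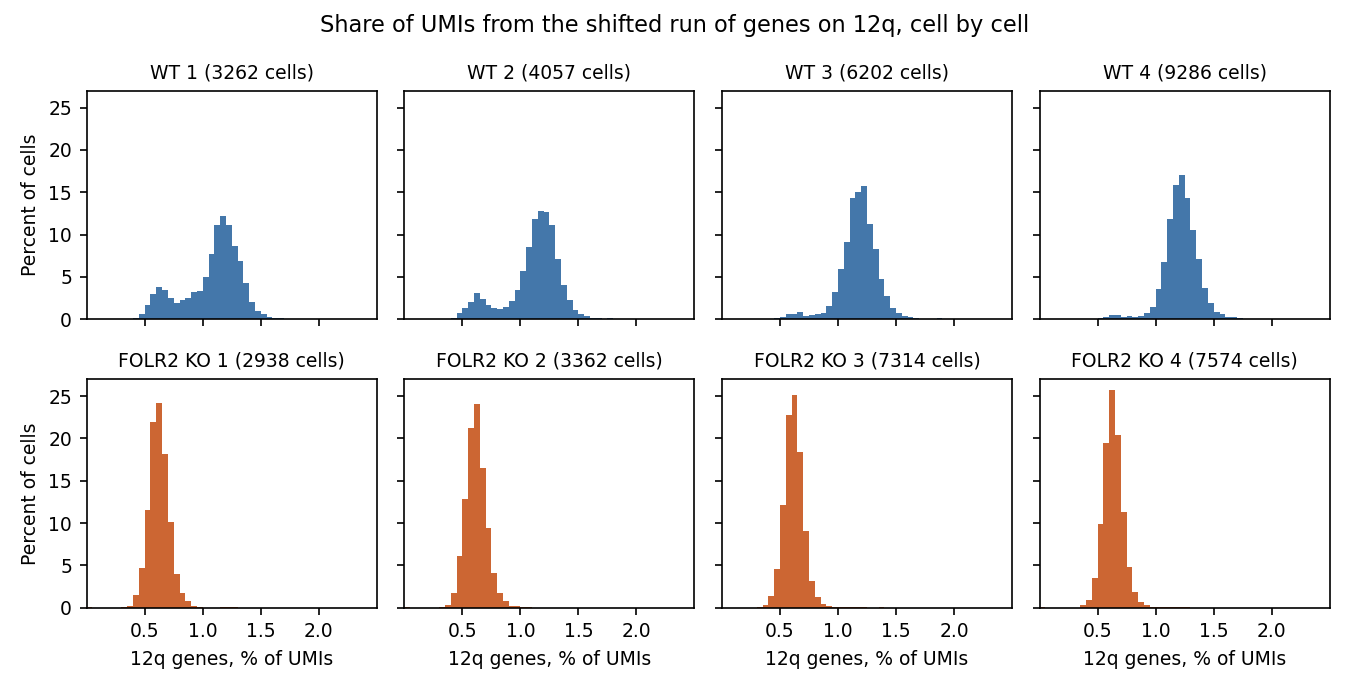
Distribution of the share of UMIs from the 166 genes of the 12q run used for sorting (percent, cells with at least 8000 UMIs) in each library. KO cells form a single low peak, and the WT libraries have a main high peak with a smaller low one.

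At the level of single cells, shares of cells with a UMI were compared after thinning each cell to 2400 UMIs, which left out 1644 WT and 2494 KO cells below that depth. IL1B was seen in 34.4% ± 1.3 of WT cells and 54.1% ± 10.4 of KO cells, and FOLR2 in 0.529% ± 0.214 and 0.0677% ± 0.0461; both had p = 0.0286 in a two-sided exact permutation test, the smallest that 4 against 4 libraries allow, and adjusted p = 0.143 over the 10 genes. Without thinning, IL1B was seen in 57.1% and 74.3% of cells and FOLR2 in 2.41% and 0.424%. CD3D, which macrophages should lack, was seen after thinning in 0.0159% of WT cells and 0.0190% of KO cells. NLRP3 was seen in 27.3% ± 2.6 and 27.8% ± 3.2 of cells, PYCARD in 13.8% ± 2.4 and 8.52% ± 2.61, GSDMD in 24.7% ± 3.9 and 20% ± 1.9, IL18 in 5.28% ± 0.34 and 5.45% ± 0.74, and the proliferation genes MKI67 in 18.0% ± 1.8 and 14.7% ± 1.3 and TOP2A in 8.16% ± 1.24 and 7.22% ± 2.25, none with an adjusted p under 0.143. The monocyte marker CD14 was seen in 1.04% ± 0.17 and 1.1% ± 0.14 and the scavenger receptor CD163 in 0.160% ± 0.087 and 0.268% ± 0.023. Of the 10 genes, 0 passed after adjustment and 2 had an unadjusted p under 0.05. With a smallest p of 0.0286, adjustment over 10 genes lets a gene pass only if most of the 10 reach that floor. That 0 passed is therefore no evidence that the shares were alike.

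The groups also differed within clusters of cells. Clustering 20000 cells, with genes centred within each library, gave 10 clusters. Cluster 4 was proliferating-like, with all 12 proliferation markers detected and TPX2, TOP2A, CDK1 and CENPF among its leading genes. Cluster 6 also had all 12 detected, with TYMS and RRM2 among its leading genes. Cluster 3 had 6 of 7 interferon-response markers detected and 5 of the 7 among its leading genes. All clusters are given by number. Of the 10 clusters, 0 differed in share between the groups after adjustment (lowest adjusted p = 0.0952, exact permutation test) and 3 had an unadjusted p under 0.05. The floor of the exact test limits these 10 adjusted values as it does those of the 10 genes. The leading genes of the clusters include genes that differ between the groups, so the sizes are not compared further. In the 8 clusters with at least 50 cells in every library, edgeR called 3114, 2752, 2691, 2521, 1160, 1013, 185 and 524 genes in clusters 1 to 8. Centring within libraries takes group differences out before clustering, so these counts do not separate a change within cell states from a shift between them. Interferon-response genes were called higher in each of the 8, with none lower and medians of 1.12 to 1.69: 25 to 29 of 30 to 35 tested members were higher in clusters 1 to 6, 13 of 22 in cluster 8 and 8 of 20 in cluster 7, where most did not pass. IL1B was called higher in 7 of the 8 (in cluster 6 its log2 change was 1.64, adjusted p = 0.0643), and NLRP3 was called in none, with adjusted p of 0.0815 to 0.989.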

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

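All weighing tests in this part, and the counts over other splits, were chosen after the results had been seen, except the test of GC content and length, whose prediction was written before its result. Over 286 groups of 4 libraries, 13 (4.55%) had a library far from the other 3, where chance gives about 5%, so these values show no more deviations than chance would.

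In CPM, the libraries far from the rest of their group were WT replicate 1 for IFIT2 (14.1 against 4.04 to 5.55), WT replicate 2 for CD36 (120.0 against 143 to 146) and NQO1 (85.1 against 76.0 to 77.5), and WT replicate 3 for ICAM1 (104.0 against 75.9 to 80.3), SQSTM1 (1303 against 1035 to 1068) and VEGFA (303 against 209.8 to 223). The others were WT replicate 4 for RNASE2 (281 against 176 to 185), KO replicate 1 for TIMP3 (23.1 against 39.8 to 42.8), KO replicate 2 for APOE (912 against 487 to 528) and KO replicate 3 for RAP2A (1.04 against 1.41 to 1.42). In shares of cells with a UMI they were KO replicate 4 for MKI67 (16.6% against 13.9% to 14.2%), KO replicate 3 for RAP2A (0.305% against 0.284% to 0.286%) and WT replicate 1 for IFIT3 (3.76% against 1.94% to 2.05%).

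The real grouping stood apart in its gene counts: 1 of 35 splits of the 8 libraries, the real one, gave as many genes higher (2165, highest other 0), lower (2342, highest other 0) or past 1.5-fold (866, highest other 0). The same held within clusters 1 to 8, where the real split gave 3114, 2752, 2691, 2521, 1160, 1013, 185 and 524 genes and the highest other 0, 0, 1, 0, 1, 1, 1 and 8, each real count being reached by 1 of 35 splits. Every other split puts WT and KO libraries in the same group, which adds the genotype difference to the spread within groups. Counts near 0 were therefore likely in advance, and these splits cannot exclude chance. For the list tests chance was not excluded: all 35 splits called at least as many lists as the real one (2, highest other 16), though not always the same lists, 5 of 35 gave a camera p for the interferon list as small (-log10 p of 15.3, highest other 28.0) and 6 of 35 for oxidative phosphorylation (3.74, highest other 5.96). The larger numbers of lists in other splits may reflect structure among the libraries, which was not tested. Counted by members, the interferon list had 30 genes higher in the real split and 0 in any other (1 of 35), but no other split called any gene, so this count restates the totals and decides nothing about the list itself.

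The first pattern weighed is the shift of neighbouring genes together in KO, which on 12q had a median of -0.90. GC content and transcript length predicted a median of 0.0534 for the genes of that run, which argues against them. A difference in copy number between the cells of the groups may account for the runs: WT cells chosen by 12q alone had a larger 5p share, by at least 1.36-fold in every library, and a smaller chromosome 21 share. The long arm of chromosome 5 followed less, with ratios of 0.867, 0.859, 0.966 and 1.01 in WT replicates 1 to 4 where KO over 12q-high WT cells gave 0.694 to 0.726, so its shift stays open. In the few 12q-high KO cells (80 and 79 in replicates 3 and 4) 5p kept its KO share (0.937% and 0.951%, against 0.915% and 0.928% in 12q-low cells), as did 21, so the regions did not go together in KO; no DNA was measured, and whether such a difference arose with the knockout or before it stays open.

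The second pattern is the 12q-low cells in the WT libraries. Counting noise around a single level would leave 5p alike in both classes, and its mean ratio was 1.40. KO cells mixed into WT libraries would carry every KO level, but over FOLR2 and 19 genes named for their fold change outside the runs, these cells had gone at most a median of 0.528 of the way from the 12q-high WT level (0) to the KO level (1) in any library (lowest 0.118). KIRREL1 had gone 0.84 of the way and FOLR2 -0.10. Of the 20 genes, 7 had gone less than 0.2 (FOLR2, PLPP3 and 5 interferon genes), 7 more than 0.5 and 0 more than 0.9. Genes outside the interferon list also lay apart, with PLPP3 at 0.13, KALRN at 0.26 and DMRT3 at 0.82. Mixing in a single proportion is therefore argued against, by interferon genes and by others. FOLR2 itself says little here, since it ran from -0.95 to 0.47 over the WT libraries on 11 to 24 UMIs in their 12q-low cells. A subpopulation of the THP-1 culture that shares part of the KO profile may be the source, as a hypothesis, and the share of such cells in the culture from which the KO line was made was not measured.

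The third pattern is the rise of interferon genes in KO. Between 12q-low and 12q-high WT cells the median of the list was -0.0997, with 1 member higher and 7 lower. Of its 35 members, 6 lie in the shifted runs. These values argue against a low 12q share raising the list within the same cell. They cannot decide about interferon passed between cells, which could raise both classes alike. Over WT replicates 1 to 4 the share of 12q-low cells fell (19.1%, 13.8%, 4.07% and 2.24%). IFIT1 in the 12q-high cells fell too (23.5, 10.1, 5.81 and 3.80 CPM), and this link was not tested. A shift in the shares of cell states stays open: the lowest median within a cluster was 1.12, but the clusters come from genes centred within libraries, which decides nothing about it. The loss of FOLR2, another difference between the KO and WT lines, and interferon made or received in the cultures could each be the source and were not tested further; the design holds no rescue, and the labels do not say how many knockout lines were used.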

How the results depend on the processing

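Alternatives restricted to some replicates, regions or cell classes, and depth as a term, were chosen after seeing the data; the others were fixed in advance. The counts of genes higher, lower and past 1.5-fold stayed within 1.5 times of 2165, 2342 and 866 under every choice fixed in advance, and each kept both list calls except where stated. Leaving out each library in turn gave 1532 to 2141 genes higher, 1770 to 2380 lower and 659 to 976 past 1.5-fold, a FOLR2 change of -2.71 to -2.23, and 2 to 6 lists (6 without WT replicate 3, 5 without WT replicate 4 or KO replicate 4). Replicates 1 and 2 alone, the shallower libraries, gave 1071, 1409 and 108 genes, 7 lists and a FOLR2 change of -2.62 (adjusted p = 0.058), and replicates 3 and 4 alone gave 1339 genes past 1.5-fold. 12q-low cells alone gave 320, 443 and 102 genes and 7 lists, and thinned 12q-high WT cells against 12q-low KO cells also gave 7 lists. The number of lists was 4 with no gene filter, 5 in cells without a proliferation UMI, 4 with fry and 0 with an estimated correlation, where the interferon list had adjusted p = 0.935 and oxidative phosphorylation adjusted p = 0.335; the estimated correlation between interferon genes was 0.776, against the preset 0.01. Of the 117 named genes other than FOLR2, 113 to 117 kept their direction and call under each choice fixed in advance, 97 to 109 of 117 when a library was left out, 75 in replicates 1 and 2 alone (41 lost the call), 101 in replicates 3 and 4 alone and 51 among 12q-low cells, where 57 lost the call and 9 changed sign. Those 9 were UNG (0.11), TMPO (0.0254), COX6A1 (0.0231), PHGDH (0.00225), HSP90B1 (0.33), NR4A3 (-0.42), HSPA1A (-0.0807), NLRP3 (-0.13) and IL18 (-0.0119); UNG, TMPO, COX6A1 and HSP90B1 lie in the 12q run, where choosing 12q-low WT cells takes the difference away by construction, as for part of the 57. In replicates 3 and 4 alone NLRP3 (-0.0469), GSDMD (0.0166) and IL18 (-0.0278), none of them called, changed sign. Differences in shares of cells, none of which passed, changed sign without thinning for NLRP3 (-2.59 percentage points), IL18 (-1.09) and CD14 (-0.240), and ran with a library left out from -0.675 to 1.48 for NLRP3, -0.129 to 0.475 for IL18 and -0.00978 to 0.120 for CD14. When genes were not centred within libraries, 7 clusters differed in share (adjusted p = 0.0449), with most of these clusters nearly empty of cells from 1 group. Within clusters, leaving out a library gave 715 to 1195 genes in cluster 5, 647 to 981 in cluster 6, 58 to 235 in cluster 7 and 306 to 543 in cluster 8. Apart from that construction, the causes of these differences were not tested.

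The labels number the replicates alike in both groups, but same-numbered libraries deviated together only in part (correlations 0.466, 0.0285, 0.194 and 0.382 for numbers 1 to 4), and only libraries 1 and 4 correlated best with their own number, so they were not treated as paired. With the replicate block, 2667 genes were higher, 2953 lower and 1090 past 1.5-fold, the 2 lists stayed called, and cluster 7 gave 294 genes.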

Other observations

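Tests in this part were chosen after the results had been seen. Of the biology not described above, a few interferon genes, chosen after their values were seen, stood at different levels in single WT libraries. IFIT1 stood at 23.5, 10.1, 5.81 and 3.80 CPM (of the total of the class) in 12q-high cells of WT replicates 1 to 4, and at 19.5, 16, 3.66 and 4.75 in their 12q-low cells. MX1 stood at 42.0, 19.9, 7.66 and 4.99 in the 12q-high cells, while IFIT3, at 16.6, 10.8, 9.55 and 9.46, was nearly level over replicates 2 to 4. In the 12q-low cells of the KO libraries IFIT1 stood at 126, 95.3, 134 and 80.5 CPM, above every WT value.

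When KO and WT were compared among 12q-low cells alone, camera called 7 lists at its preset correlation. An estimated correlation, which left 0 lists called over all cells, was not tried there, and other splits of the libraries called up to 16 lists, so these calls are weak. Beside interferon genes (adjusted p = 3.1e-27) and oxidative phosphorylation (adjusted p = 0.0028) they were lysosome, S phase, G2 and M phase, heat shock and immediate early genes, with adjusted p from 0.0013 to 0.020. The receptor tyrosine kinase AXL had a log2 change of 2.19 among 12q-low cells and 1.22 over all cells.

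A hypothesis is that part of the difference between KO and WT libraries was already present among WT cells. Of 628 genes past 1.5-fold outside the shifted runs, with 12q-high WT cells split into separate sets for the comparisons with KO and with 12q-low WT cells, 440 (70.1%) were called in the same direction between 12q-low and 12q-high WT cells, 8 in the opposite one and 180 were not called; independent lists would share 19.4%. The median ratio of the log2 changes was 0.50. The KO line may therefore derive from a cell related to this WT minority, in which case the effect of the line and that of FOLR2 loss are confounded in the comparison of all cells. The genes still called among 12q-low cells, P2RX7, PLPP3, RAP2A and the interferon genes among them, would not be covered by the levels seen in that minority. These data do not say which of them depend on FOLR2.

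FOLR2 kept 18.1% of its WT level in KO, and exchange of probes or cells between pooled libraries was considered as its source. Such exchange would leave at least the same percent of every gene that is high in WT, but PLPP3 kept 0.639%, GLDN 2.01% and P2RX7 1.25%. Exchange in proportion to the WT level therefore does not account for the FOLR2 UMIs that were left. In 12q-low cells of KO replicates 1 to 4, FOLR2 stood at 0.639, 0.137, 0.406 and 0.385 CPM of the class total. PLPP3 stood at 0.231, 0.107, 0.0964 and 0.237 there, so both levels were low. The percentages cannot decide about a source that does not scale with the WT level, which was not tested. Transcript that keeps its probed part may be counted in KO, which was not tested either.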
